A study of Mus musculus with 8 samples.

How the data were processed

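RNA of MLP-29 cells, a mouse liver progenitor line, was measured on Illumina Mouse8 V2 bead arrays, which read 1 colour. The 8 arrays fell into 4 groups of 2 by their labels: control medium, and HGF for 1, 6 and 24 h, each with a replicate a and a replicate b. Per the labels' protocols, the cells were starved before stimulation, the time course was arranged so that all cultures were lysed together, and it was repeated to give the biological replicates. The p-value of a gene here rests on the spread between these 2 repeats, pooled over the groups and moderated over all genes. The camera p-value of a gene list compares its members with the other genes, so its size does not measure the spread between the repeats.

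Both deposited tables were used. The non-normalized table holds, for each of 25697 probes and 8 arrays, a summary signal, which is a linear intensity neither background subtracted nor normalized between arrays as deposited, and a detection p-value, which the authors exported with it and which compares the probe with the negative control beads of the same array. The other table holds the authors' normalized intensity, on a linear scale and not centred. Each of its columns kept the rank order of its own raw array (Spearman correlation 1.00) and had a median of 129.8 or 129.9, so scale and centring were settled from the values, while the normalization method of the authors is not given in the sources used here. The submitters' processing notes name GenomeStudio 1.9.0. No per-sample column was left out.

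Probes were named through the platform annotation supplied with the data: 23978 probes had 1 gene symbol, 0 several and 1719 none. Of these, 23962 were matched by gene identifier to a current mouse gene table, and 0 symbols changed. In limma 3.58.1 (R 4.3.3), the raw intensity was background corrected by normexp with parameters inferred from the detection p (offset 16), quantile normalized and put on the log2 scale. Fold changes are therefore on a log2(corrected signal + 16) scale, which understates the change of dim genes. A probe was kept if its detection p was under 0.05 on both arrays of at least 1 group (11325 probes), and each gene was represented by its probe with the highest mean signal (8183 of 16593 genes). Other probes of a gene were called in the opposite direction for 2 genes at 6 h, Bcl2l12 and Tdrd3. A gene undetected on every array of 1 group was given a lower bound, the brighter group's mean log2 value against the dim group's mean of, per array, the higher of the lowest detected signal and the gene's own. No fold is given where both groups were undetected.

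Each time was compared with control, and the times with each other, by lmFit and eBayes over all 8 arrays (4 residual degrees of freedom), without a block in the main design, with Benjamini-Hochberg adjustment over all genes tested. Gene lists were tested by camera with a preset correlation of 0.01, adjusted over 28 lists and 3 times together (84 tests). The tests between times were adjusted on their own. Of 31 lists fixed before the data were examined, 3 had under 5 measured members and are described by values. The lists cover immediate early genes, MAPK feedback, proteases, integrins, extracellular matrix, epithelial junctions, mesenchymal transition, actin and SRF targets, DNA replication, mitosis, G1 cyclins and inhibitors, ribosome biogenesis, ribosomal proteins, cholesterol, fatty acids, hepatocyte, cholangiocyte and progenitor, haematopoietic, endothelial and stellate markers, inflammatory and NF-kB targets, interferon-stimulated genes, growth factors and receptors, TGF-beta and BMP, Wnt, Notch and YAP, glycolysis and hypoxia, FoxO, amino acid response, ER chaperones, oxidative stress and apoptosis. With the correlation estimated from the data, 2 of 28 list calls against control held.

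Genes named in the text follow a rule fixed at the same point: the 10 steepest rises and falls per time among called genes whose HGF arrays both lay beyond both control arrays, up to 4 members of smallest adjusted p per list and time, the 5 steepest changes each way between times, and a fixed set of 26 genes, some left out for length. Of the fixed set, Spp1, Snai2 and Mki67 had no named probe, and 1 gene is not reported here. At 24 h, where no gene was called without a block, the first part of the rule was applied to the blocked fit after its values were seen. Genes outside the rule, chosen after their values were seen, are Per2 in a figure, Phgdh and Trib3, Coro1a and Eng, and the genes that the closing part says were chosen so.

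The labels say that the whole time course was repeated to give the replicates. That a letter marks the same repeat in every group is implied by them and not stated. The difference of replicate a minus replicate b correlated across genes between every pair of groups, at 0.194 to 0.443. The fit with the letter as a block is given where it changed a call or moved a count of calls by over 1.5 times. Alternatives were other scalings and background settings, the authors' normalized values, other filters, all probes, only the groups compared, other variance models, a test against a 1.5-fold change, other set tests and leaving out each array. Chosen after seeing the data were the authors' values with the block, a random block, and the lists without each array. Overlaps between times were set beside 100 simulations of unchanged groups against the same controls.

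The procedure was tested on 20 simulated data sets of the comparison at 1 h against control, with 8183 genes, 200 of them changed. It recovered 25.6% of genes changed 1.5-fold, 84.7% of those changed 2-fold and 99.6% of those changed 4-fold, with 5.76% of calls false, and found a list of 25 genes shifted by 0.5 on the log2 scale in 100% of the sets. Genes and arrays varied independently in these sets, without the correlation between genes or the replicate difference seen in the data. The recovery, false-call and list figures hold for that setting only. The number of arrays limits the precision. Slide positions and batches of the arrays are not given in the sources used here and were not tested. The 1719 probes with no symbol stayed out of the counts of genes.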

Results

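The series followed the transcriptional response of MLP-29 cells, a mouse liver progenitor cell line, to hepatocyte growth factor (HGF), the ligand of the receptor tyrosine kinase Met. Starved cells were kept in control medium or given HGF for 1, 6 or 24 h, and all cultures were lysed together. Each of the 4 groups held 2 biological replicates, a and b, each on 1 Illumina mouse bead array, so that 8 arrays were compared. Of 25697 probes, 11569 to 11893 were detected per array (45.0% to 46.3%), and the median raw signal lay between 113 and 138 intensity units. The 2 arrays of a group correlated at 0.990 to 0.993 across genes, and arrays of different groups at 0.965 to 0.987. On the first principal component (36.9% of the variance) the 6 h arrays stood apart, and on the next (29.6%) the 1 h arrays.

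In all, 8183 genes were tested. Changes are given as log2 fold change against control ± SE from the fit over all 8 arrays, with 2 arrays per group, and genes are called at a Benjamini-Hochberg adjusted p under 0.05 from limma. A gene not detected on either array of 1 group has a lower bound in place of a fold. The moderated F test called 1929 genes at some time (2829 with the replicate letter as a block, 1243 with median scaling of the arrays and 992 without HGF 6 h replicate a).

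**Figure D1:**
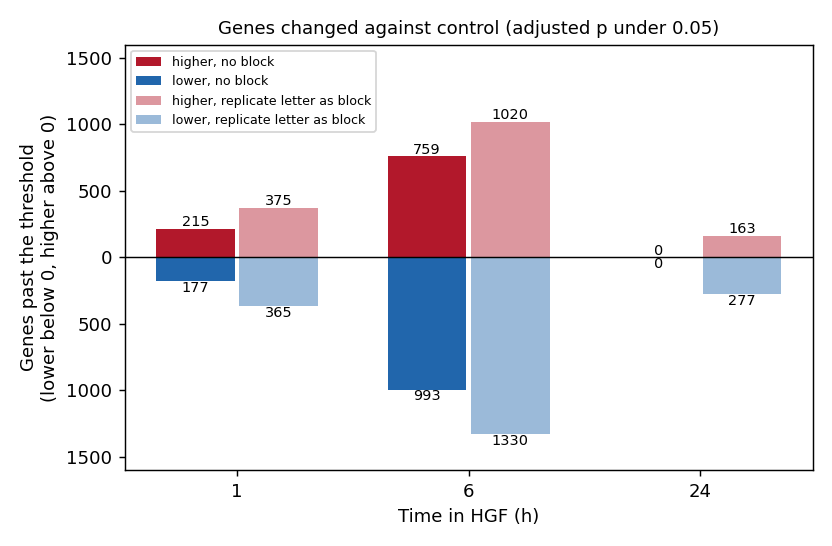
Number of genes past the threshold (y axis, higher above 0 and lower below 0) at each time in HGF against control (x axis, hours), without and with the replicate letter as a block. The counts are highest at 6 h (759 higher and 993 lower without the block), and at 24 h genes pass only with the block (163 and 277).

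After 1 h in HGF, 215 genes were higher and 177 lower than in control cells, and 122 of the higher and 60 of the lower ones differed by at least 2-fold. The question was which transcripts change early after HGF is given. The control group had no time point of its own, so handling at the start of stimulation cannot be told apart from HGF. Among the steepest rises were transcription factors of the immediate early response. Fosb (8.36 ± 0.30) and Fos (6.02 ± 0.44), 2 subunits of the AP-1 transcription factor, rose with adjusted p = 1.16e-05 and 0.00053. Egr2, which was not above background in control cells, rose at least 145-fold (adjusted p = 2.74e-07). Egr1 (3.45 ± 0.22, adjusted p = 0.000235), Fosl1 (2.79 ± 0.21), Atf3 (5.09 ± 0.48), Myc (1.38 ± 0.22) and the matricellular protein gene Ccn1 (3.46 ± 0.12) rose as well. In the list of immediate early genes, 22 of 31 measured members rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 change of 1.61. Camera gave the list an adjusted p = 9.54e-31, and adjusted p = 0.0331 with an estimated correlation.

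Secreted ligands and cytokines followed. Csf2, the gene of the cytokine GM-CSF, rose at least 92.9-fold from below background (adjusted p = 5.1e-05), and Lif (5.66 ± 0.17, adjusted p = 6.54e-06), a cytokine of the interleukin-6 family, rose from a detected level. The prostaglandin synthase gene Ptgs2 and the chemokine gene Cxcl2, neither above background in control cells, rose at least 3.27-fold and at least 2-fold. Of the inflammatory cytokines and NF-kB targets, 14 of 37 measured members rose and 0 fell (26 and 1 adjusted over the list alone; 24 and 1 with the block), with a median of 0.99. For this list, camera gave an adjusted p = 1.5e-21, and adjusted p = 0.154 with an estimated correlation. Among the growth factors and their receptors, 6 of 33 measured members rose and 0 fell (7 and 0 adjusted over the list alone): the EGF receptor ligand Hbegf (3.28 ± 0.19, adjusted p = 0.000125), Mst1r (2.90 ± 0.13, adjusted p = 2.71e-05), which encodes a receptor tyrosine kinase related to Met, Pdgfb (2.00 ± 0.15), and Ereg (at least 2.6-fold) were examples. By camera, the list had an adjusted p = 0.00144, and adjusted p = 0.159 with an estimated correlation. Nppb, the gene of a natriuretic peptide, rose at least 10.3-fold. Met itself, the receptor of HGF, gave -0.04 ± 0.23 (adjusted p = 0.946).

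Some feedback regulators of receptor and MAP kinase signalling rose too. Errfi1 (3.61 ± 0.16, adjusted p = 2.71e-05), an inhibitor of the EGF receptor, Phlda1 (2.82 ± 0.12), and the phosphatase gene Dusp6 (2.38 ± 0.27) were among the members of the MAPK feedback list, of which 6 of 22 measured members rose and 1 fell (11 and 2 adjusted over the list alone; 10 and 1 with the block). This list had a camera adjusted p = 2.49e-05, and adjusted p = 0.138 with an estimated correlation. Of the plasminogen activation and matrix protease genes, 7 of 26 measured members rose and 0 fell (7 and 0 adjusted over the list alone). The collagenase gene Mmp13 (4.38 ± 0.69, adjusted p = 0.0138), the stromelysin genes Mmp10 (3.56 ± 0.28) and Mmp3 (2.73 ± 0.21), the urokinase receptor gene Plaur (1.52 ± 0.14) and the cathepsin gene Ctsl (0.95 ± 0.12) were among the 7. Tested by camera, the list had an adjusted p = 0.00233, and adjusted p = 0.209 with an estimated correlation. In the list of actin cytoskeleton genes and SRF targets, 4 of 27 measured members rose and 1 fell (6 and 2 adjusted over the list alone; 4 and 2 with the block), including Ankrd1 (1.06 ± 0.11), Srf (1.06 ± 0.17), Fhl2 (1.01 ± 0.17) and Rnd1 (at least 2.19-fold; camera adjusted p = 0.000728, and adjusted p = 0.209 with an estimated correlation). The ER chaperone list was called upward with 0 members past the threshold one by one (1 rose adjusted over the list alone and 1 with the block; median 0.25; camera adjusted p = 0.00030, and adjusted p = 0.217 with an estimated correlation). The TGF-beta and BMP list was called with Skil (1.02 ± 0.13) and Smad6 (0.78 ± 0.13) higher, where 2 of 16 measured members rose and 0 fell (3 and 0 adjusted over the list alone). In the camera test it had an adjusted p = 0.044, and adjusted p = 0.217 with an estimated correlation. Its camera adjusted p was 0.0625 with the replicate letter as a block. The call held in 6 of 8 fits with 1 array left out in turn, and not without HGF 1 h replicate b.

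The genes that fell by 1 h included many of mitosis. Of 38 measured mitosis genes, 25 fell and 0 rose (35 and 0 adjusted over the list alone), with a median of -0.82. Camera gave the list an adjusted p = 1.43e-21, and adjusted p = 0.209 with an estimated correlation. Examples were the spindle checkpoint kinase genes Ttk (-1.47 ± 0.21, adjusted p = 0.00938) and Bub1b (-0.98 ± 0.15), the cohesin protector gene Sgo1 (-0.97 ± 0.14) and the kinetochore gene Spc25 (-0.82 ± 0.13). Of 46 DNA replication genes, 1 fell, Dbf4 (-0.62 ± 0.11), and the list was not called (median -0.13; camera adjusted p = 0.341). Outside these lists, Edn1 (-2.93 ± 0.28, adjusted p = 0.00167), which encodes the peptide endothelin 1, fell. Pde4b, a cyclic AMP phosphodiesterase gene not above background at 1 h, fell at least 2.71-fold. The ubiquitin ligase gene Fbxo32 (-1.54 ± 0.20) and the cyclin gene Ccng2 (-1.13 ± 0.18), both in the FoxO list, fell, and in that list 1 of 24 measured members rose and 3 fell (1 and 5 adjusted over the list alone; 2 and 5 with the block; camera adjusted p = 0.301). The zinc finger genes Zkscan14 (-2.11 ± 0.26), Zfp235 (-1.55 ± 0.33) and Zfp60 (-1.48 ± 0.33) fell, as did the histone genes H2ac21 (-1.54 ± 0.24), H2ac11 (-1.53 ± 0.30) and H2ac22 (-1.48 ± 0.22), whose near-identical copies leave it uncertain which copy each probe measured.

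The other lists were not called at 1 h. Among the G1 cyclins and cell cycle inhibitors, 3 of 19 measured members rose and 1 fell (3 and 1 adjusted over the list alone). The cyclin-dependent kinase inhibitor gene Cdkn1a (1.43 ± 0.13, adjusted p = 0.00136), the antiproliferative gene Tob1 (1.32 ± 0.12) and the p53 regulator gene Mdm2 (0.87 ± 0.13) were the 3 that rose, and Ccng2 the 1 that fell. For the other lists, the numbers that rose and fell are given first and, in brackets, those adjusted over the list alone. Integrins and focal adhesion had 0 and 1 of 34 (2 and 1; 3 and 1 with the block), epithelial junctions 1 and 0 of 27 (1 and 0), mesenchymal transition 1 and 0 of 15 (1 and 0) and extracellular matrix 0 and 0 of 18 (0 and 0; 0 and 3 with the block). Ribosome biogenesis had 2 and 0 of 53 (2 and 0) and ribosomal proteins 0 and 0 of 49 (0 and 0). Cholesterol synthesis had 0 and 0 of 18 (0 and 0) and fatty acid synthesis 0 and 0 of 18 (0 and 0). Interferon-stimulated genes had 1 and 1 of 24 (2 and 2; 2 and 2 with the block) and Wnt, Notch and YAP targets 2 and 0 of 12 (2 and 1; 2 and 2 with the block). Glycolysis and hypoxia had 2 and 0 of 25 (3 and 0; 4 and 0 with the block) and the amino acid response 1 and 0 of 28 (1 and 0; 2 and 0 with the block). Oxidative stress had 0 and 1 of 26 (0 and 1; 2 and 1 with the block) and apoptosis regulators 2 and 0 of 21 (2 and 1; 5 and 2 with the block). In the mesenchymal transition list the member that rose was Snai1 (at least 1.87-fold from below background), the gene of a repressor of E-cadherin. The E-cadherin gene Cdh1 gave 0.07 ± 0.12 (adjusted p = 0.785) and Ccnd1, the gene of cyclin D1, 0.06 ± 0.14 (adjusted p = 0.863). With the replicate letter as a block, 375 genes were higher and 365 lower at 1 h. Leaving out 1 array lowered the counts most without control replicate a, to 73 higher and 6 lower, and leaving out some single array ended the calls of Bub1b, Ccng2, Ctsl, Dbf4, Fbxo32, Fhl2, H2ac11, H2ac21, H2ac22, Mdm2, Mmp13, Myc, Sgo1, Skil, Smad6, Snai1, Spc25, Srf, Ttk, Zfp235, Zfp60 and Zkscan14 (adjusted p up to 0.206).

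**Figure D2:**
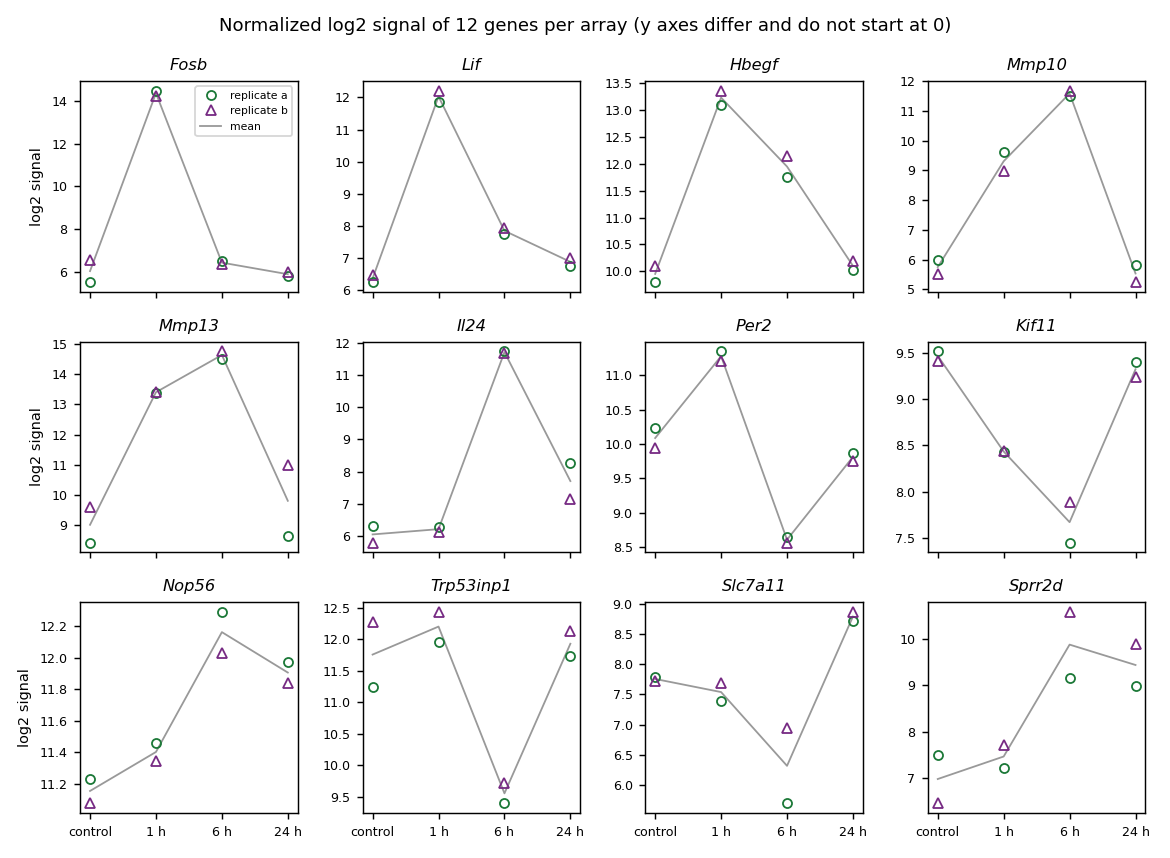
Normalized log2 signal (y axis, a scale for each gene) of 12 genes on each of the 8 arrays (circles, replicate a; triangles, replicate b; line, mean of the 2) in control cells and after 1, 6 and 24 h in HGF (x axis). Fosb, Lif and Hbegf are highest at 1 h, Mmp10, Mmp13 and Il24 at 6 h, and Per2, Kif11, Trp53inp1 and Slc7a11 are lowest at 6 h.

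After 6 h, 759 genes were higher and 993 lower than in control cells, 194 and 285 of them by at least 2-fold. Genes of secreted proteases were among the steepest rises. Mmp10 (5.84 ± 0.28, adjusted p = 0.000195), Mmp13 (5.62 ± 0.69) and Mmp3 (5.09 ± 0.21, adjusted p = 0.000111) rose, as did Timp1 (2.23 ± 0.14), which encodes an inhibitor of these enzymes, Plaur (1.30 ± 0.14) and Ctsl (1.43 ± 0.12). The urokinase gene Plau and the gelatinase gene Mmp9, not above background in control cells, rose at least 2.13-fold and at least 1.62-fold. Of the protease list, 13 of 26 measured members rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.51. For this list, camera gave an adjusted p = 0.000153, and adjusted p = 0.159 with an estimated correlation. The serine protease gene Tmprss2 (-3.42 ± 0.67), in the same list, fell. Other leading rises were the cytokine gene Il24 (5.64 ± 0.33, adjusted p = 0.000363), Csf2 (at least 7.74-fold), the chemokine gene Ppbp (3.19 ± 0.40), S100a7a (3.18 ± 0.67), Fxyd5 (3.17 ± 0.22), Pbp2 (at least 7.59-fold) and the scaffold protein gene Akap12 (at least 7.04-fold).

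Adhesion and cytoskeletal genes rose in part. Of the integrin and focal adhesion list, 9 of 34 measured members rose and 2 fell (11 and 5 adjusted over the list alone). The hyaluronan receptor gene Cd44 (1.49 ± 0.15, adjusted p = 0.00135) and the integrin genes Itga6 (1.48 ± 0.18) and Itgav (1.24 ± 0.21) were higher and Itgb7 (-1.26 ± 0.16) was lower. By camera, the list had an adjusted p = 0.0171, and adjusted p = 0.209 with an estimated correlation. Of the actin and SRF list, 10 of 27 measured members rose and 3 fell (16 and 3 adjusted over the list alone), with Cnn2 (1.20 ± 0.20), Tpm3 (0.84 ± 0.14), Ankrd1 (0.79 ± 0.11) and Myl12a (0.77 ± 0.12) higher. This list had a camera adjusted p = 0.00117, and adjusted p = 0.217 with an estimated correlation. Of the extracellular matrix genes, 7 of 18 measured members rose and 2 fell (8 and 2 adjusted over the list alone). The collagen genes Col7a1 (1.31 ± 0.14), Col5a1 (0.99 ± 0.16), Col18a1 (0.72 ± 0.11) and Col4a1 (0.59 ± 0.11) were among the 7. Tested by camera, the list had an adjusted p = 0.044, and adjusted p = 0.479 with an estimated correlation. With the block its camera adjusted p was 0.0534. The call held in 5 of 8 fits with 1 array left out in turn, and not without control replicate b. In the mesenchymal transition list, which was not called (camera adjusted p = 0.187), 3 of 15 measured members rose and 0 fell (3 and 0 adjusted over the list alone), namely Snai3 (0.95 ± 0.18), the intermediate filament gene Vim (0.74 ± 0.15) and Zeb1 (0.53 ± 0.13). The junction list was not called either, with 2 and 1 of 27 (2 and 1 adjusted over the list alone; 3 and 3 with the block) rising and falling. Its members Gja1 (1.09 ± 0.19) and Elf3 (0.80 ± 0.15) rose and Tjp3 (-1.10 ± 0.22) fell, while Cdh1 gave -0.17 ± 0.12 (adjusted p = 0.354). The integrin genes Itga2 (0.53 ± 0.38, adjusted p = 0.353, and 0.0395 with the block) and Itga3 (0.02 ± 0.13, adjusted p = 0.914) were not called.

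Ribosome biogenesis genes rose as a group at 6 h. Of these, 32 of 53 measured members rose and 0 fell (37 and 0 adjusted over the list alone), with a median of 0.60. In the camera test it had an adjusted p = 1.31e-14, and adjusted p = 0.0331 with an estimated correlation. The snoRNP and nucleolar genes Nop56 (1.01 ± 0.14, adjusted p = 0.00365), Lyar (0.99 ± 0.14), Gar1 (0.95 ± 0.12) and Grwd1 (0.84 ± 0.12) were examples. Of the cytosolic ribosomal protein genes, 1 of 49 measured members rose and 0 fell (0 and 0 adjusted over the list alone; 2 and 0 with the block), and the list was not called (camera adjusted p = 0.803). Of the ER chaperone list, 8 of 18 measured members rose and 1 fell (9 and 2 adjusted over the list alone; 10 and 2 with the block), including Creld2 (1.72 ± 0.25), Calr (1.69 ± 0.17), Hyou1 (1.64 ± 0.16) and Pdia4 (1.11 ± 0.19). Camera gave the list an adjusted p = 0.000947, and adjusted p = 0.237 with an estimated correlation. Immediate early genes were mixed: 12 of 31 measured members rose and 5 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.00495, and adjusted p = 0.237 with an estimated correlation), with Fosl1 (2.26 ± 0.21), Egr2 (at least 3-fold), Egr1 (0.91 ± 0.22) and Myc (0.81 ± 0.22) higher, Klf4 (-1.17 ± 0.15) lower and Fos at 0.71 ± 0.44 (adjusted p = 0.284). Of the MAPK feedback list, 9 of 22 measured members rose and 0 fell (9 and 0 adjusted over the list alone; 10 and 1 with the block; camera adjusted p = 0.000852, and adjusted p = 0.159 with an estimated correlation), with Errfi1 (2.13 ± 0.16), Dusp14 (1.28 ± 0.14) and Lrig1 (1.16 ± 0.13) among them. Of the growth factor list, 12 of 33 measured members rose and 5 fell (12 and 6 adjusted over the list alone), with Hbegf (2.00 ± 0.19), Mst1r (1.54 ± 0.13) and Igfbp3 (at least 4.46-fold from below background) higher and Vegfb (-1.38 ± 0.13) lower. For this list, camera gave an adjusted p = 0.0469, and adjusted p = 0.217 with an estimated correlation. The call held in 4 of 8 fits with 1 array left out in turn. Met gave 0.27 ± 0.23 (adjusted p = 0.453).

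Mitosis genes were low at 6 h too. Of 38, 35 fell (38 adjusted over the list alone) and none rose, with a median of -1.18. By camera, the list had an adjusted p = 2.14e-20, and adjusted p = 0.209 with an estimated correlation. The kinesin genes Kif11 (-1.79 ± 0.16, adjusted p = 0.00125) and Kif4 (-1.19 ± 0.11), the kinase gene Melk (-1.59 ± 0.15) and the spindle gene Spag5 (-1.30 ± 0.13) were examples. DNA replication genes went both ways, with 7 and 6 of 46 (10 and 8 adjusted over the list alone) rising and falling (median -0.03, mean 0.01; camera adjusted p = 0.956): Orc6 (0.60 ± 0.11) rose, and Dbf4 (-0.97 ± 0.11), Pole (-0.77 ± 0.14) and Rfc5 (-0.60 ± 0.11) fell. Of the G1 cyclins and inhibitors, 0 of 19 measured members rose and 8 fell (1 and 9 adjusted over the list alone; 1 and 9 with the block). Trp53inp1 (-2.21 ± 0.34), the inhibitor genes Cdkn2d (-1.42 ± 0.23) and Cdkn2c (-1.18 ± 0.20), and Rb1 (-0.72 ± 0.11), the retinoblastoma gene, were among the 8. This list had a camera adjusted p = 0.0469, and adjusted p = 0.217 with an estimated correlation. With the block its camera adjusted p was 0.0523. The call held in 4 of 8 fits with 1 array left out in turn, and not without HGF 6 h replicate a. Ccnd1 gave 0.30 ± 0.14 (adjusted p = 0.173).

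Some genes of starvation and lipid metabolism fell at 6 h. Of the FoxO targets, 1 of 24 measured members rose and 12 fell (2 and 15 adjusted over the list alone; 3 and 14 with the block): the autophagy gene Gabarapl1 (-1.57 ± 0.17, adjusted p = 0.00161), Hbp1 (-1.23 ± 0.17), Sesn1 (-1.05 ± 0.13) and Klhl24 (-0.98 ± 0.13) fell, and Bcl2l11 (0.87 ± 0.14), which encodes the proapoptotic protein Bim, rose. Tested by camera, the list had an adjusted p = 0.00188, and adjusted p = 0.217 with an estimated correlation. Of the fatty acid list, 2 of 18 measured members rose and 7 fell (2 and 12 adjusted over the list alone; 2 and 11 with the block), with the acetyl-CoA synthetase gene Acss2 (-1.68 ± 0.20), the desaturase gene Fads1 (-0.98 ± 0.11), Elovl5 (-0.77 ± 0.11) and Me1 (-0.75 ± 0.13) lower. In the camera test it had an adjusted p = 0.0155, and adjusted p = 0.209 with an estimated correlation. Of the cholesterol genes, 0 of 18 measured members rose and 2 fell (0 and 2 adjusted over the list alone; 0 and 7 with the block), namely Lss (-0.95 ± 0.20) and Fdps (-0.70 ± 0.16). Camera gave the list an adjusted p = 0.0359, and adjusted p = 0.792 with an estimated correlation. Leaving out HGF 6 h replicate a ended the calls of the cholesterol and fatty acid lists. With 1 array left out in turn, these calls held in 6 of 8 and 7 of 8 fits. Of the amino acid response genes, 0 of 28 measured members rose and 9 fell (0 and 10 adjusted over the list alone; 1 and 13 with the block), with Slc7a11 (-1.44 ± 0.35), Nupr1 (-1.31 ± 0.19), Vldlr (-0.87 ± 0.18) and Aars (-0.56 ± 0.14) lower. For this list, camera gave an adjusted p = 0.00822, and adjusted p = 0.722 with an estimated correlation. The call held in 6 of 8 fits with 1 array left out in turn, and not without HGF 6 h replicate a. Other steep falls were the lipid droplet gene Plin4 (-2.94 ± 0.32), the glutamine synthetase gene Glul (-2.38 ± 0.28), the glucocorticoid-induced gene Tsc22d3 (-2.37 ± 0.20), Depp1 (-3.23 ± 0.60), Pdzk1ip1 (-2.53 ± 0.37), Kcne2 (-2.53 ± 0.19), Fam107a (at least 7.85-fold) and Ncald (at least 4.69-fold).

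The remaining lists were not called at 6 h. For inflammatory cytokines and NF-kB targets, 9 and 4 of 37 (10 and 4 adjusted over the list alone) rose and fell (camera adjusted p = 0.0547, and 0.0378 with the block; adjusted p = 0.64 with an estimated correlation), with Lif (1.48 ± 0.17) and Cxcl5 (at least 2.52-fold) higher. Of the interferon-stimulated genes, 2 and 5 of 24 (2 and 7 adjusted over the list alone) rose and fell, with Ifit2 lower by at least 3.33-fold and Parp14 (-0.80 ± 0.13), Parp12 (-0.83 ± 0.14) and Ddx58 (-0.78 ± 0.18) lower. Of the oxidative stress genes, 0 and 7 of 26 (0 and 7 adjusted over the list alone) rose and fell, with Gclm (-0.78 ± 0.11), Gclc (-0.90 ± 0.16), Ephx1 (-0.85 ± 0.16) and Cat (-0.63 ± 0.13) lower. For apoptosis regulators the numbers were 4 and 4 of 21 (4 and 6 adjusted over the list alone), with Bbc3 (-1.29 ± 0.23) and Bid (-0.73 ± 0.17) lower and Casp8 (0.68 ± 0.18) higher. They were 2 and 1 of 16 (2 and 1 adjusted over the list alone; 3 and 2 with the block) for the TGF-beta and BMP list, with Ltbp1 (0.96 ± 0.11) and Acvr1 (0.55 ± 0.15) higher and Id3 (-1.24 ± 0.31) lower. Wnt, Notch and YAP targets had 3 and 1 of 12 (3 and 1 adjusted over the list alone; 3 and 2 with the block). They were 2 and 3 of 25 (2 and 3 adjusted over the list alone; 4 and 5 with the block) for glycolysis and hypoxia, with Pfkfb4 (1.48 ± 0.13) higher and Pfkm (-0.98 ± 0.15), Ndrg1 (-1.10 ± 0.27) and Mxi1 (-0.89 ± 0.22) lower. Scaling the arrays to 1 median in place of quantile normalization gave 322 higher and 963 lower genes at 6 h (25.1% of calls higher against 43.3%), with the median over all genes at -0.16 against -0.03. Leaving out some single array lowered the 6 h counts, for example to 380 higher and 477 lower without HGF 6 h replicate b, and ended the calls of Aars, Acvr1, Bbc3, Bid, Casp8, Cat, Col4a1, Ddx58, Depp1, Egr1, Elf3, Ephx1, Fdps, Id3, Lss, Mxi1, Myc, Ndrg1, Pole, Rfc5, S100a7a, Slc7a11, Snai3, Tjp3, Tmprss2, Vim, Vldlr and Zeb1 (adjusted p up to 0.18).

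**Figure D3:**
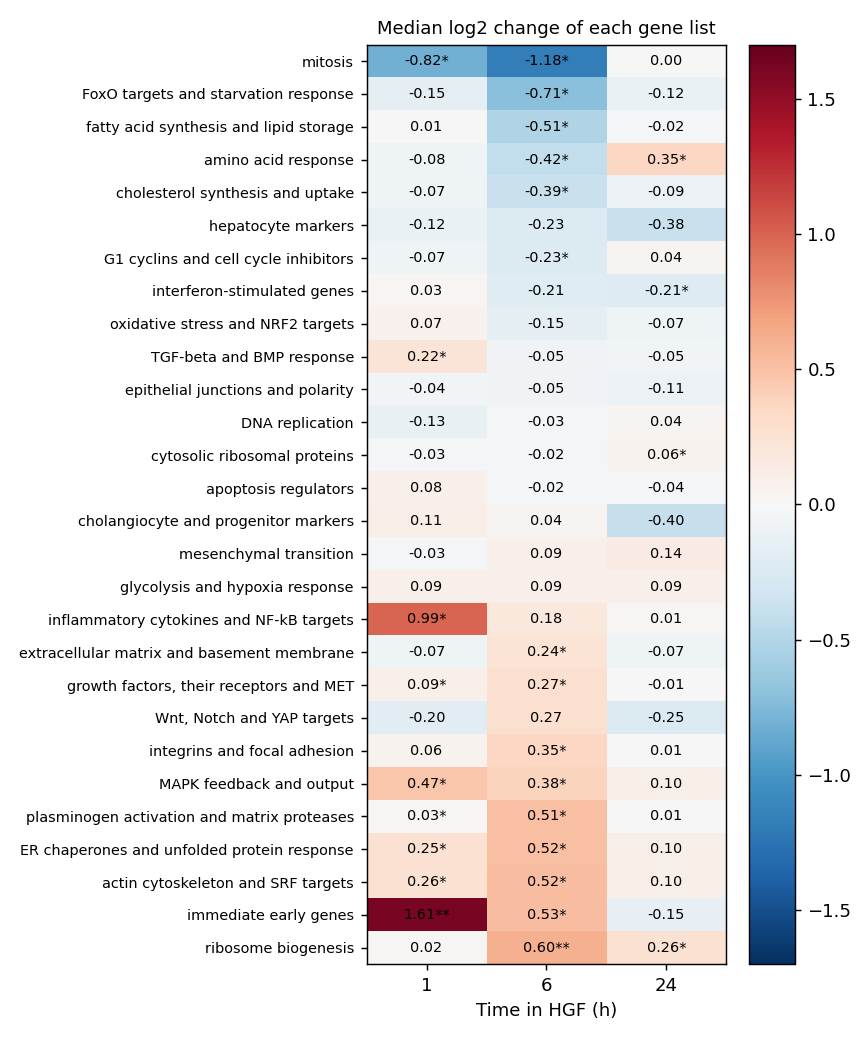
Median log2 change against control (colour and number) of the measured members of 28 gene lists (rows, ordered by the value at 6 h) at 1, 6 and 24 h in HGF (columns). A star marks a camera adjusted p under 0.05 and a second star one that also passes with an estimated correlation, which holds for immediate early genes at 1 h (1.61) and ribosome biogenesis at 6 h (0.60).

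At 24 h, limma called 0 genes in either direction without the replicate block, and the smallest adjusted p was 0.0801. An unadjusted p under 0.05 was reached by 1626 genes (19.9%), and 114 genes had a difference of at least 2-fold in either direction whatever their p, against 235 at 1 h and 517 at 6 h. The authors' normalized values gave 26 higher and 38 lower, no background correction 37 and 62, and a variance trend with intensity 55 and 75. With the replicate letter as a block, 163 genes were higher and 277 lower, 30 and 70 of them by at least 2-fold. A random block gave 44 and 56, and the authors' values with the block 326 and 503, both chosen after seeing the data. The adjusted p of the genes named next are from that fit, to which the rule for naming genes was applied after its values were seen. The leading rises were the small proline-rich protein genes Sprr2d (2.47 ± 0.54, adjusted p = 0.0431) and Sprr2e (2.38 ± 0.57, adjusted p = 0.0404), the chemokine gene Ppbp (2.25 ± 0.40, adjusted p = 0.0269), and Cth (2.16 ± 0.61, adjusted p = 0.00527), the gene of cystathionine gamma-lyase. S100a7a (1.76 ± 0.67, adjusted p = 0.0425), Cdsn (1.73 ± 0.55, adjusted p = 0.0281), Il24 (1.65 ± 0.33, adjusted p = 0.0207), Urah (1.57 ± 0.36, adjusted p = 0.018) and Sprr2k (1.46 ± 0.27, adjusted p = 0.0171) rose as well, and Gap43 rose at least 2.27-fold. The SE beside each log2 change is that of the fit without the block.

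Among the steepest falls in the blocked fit were Gkn2 (-2.54 ± 0.95, adjusted p = 0.00458), which encodes a gastric mucosal protein, and Tmprss2 (-2.44 ± 0.67, adjusted p = 0.0113). Prelp (-2.31 ± 0.85, adjusted p = 0.00692), Anxa13 (-1.97 ± 0.89, adjusted p = 0.0404), Mmp3 (-1.87 ± 0.21, adjusted p = 0.0113), Fhl1 (-1.87 ± 0.35, adjusted p = 0.00481), Bcas1 (-1.86 ± 0.86, adjusted p = 0.0189) and Ppp1r1b (-1.85 ± 0.75, adjusted p = 0.0189) fell too. Lypd2 and Sult1a1, not above background at 24 h, fell at least 3.1-fold and at least 2.23-fold. Myc (0.66 ± 0.22, adjusted p = 0.0358) and Vim (0.69 ± 0.15, adjusted p = 0.0332) were higher and Sox9 (-1.30 ± 0.32, adjusted p = 0.0147), a transcription factor gene of biliary and progenitor cells, was lower. Without the block these 3 had adjusted p = 0.182, 0.0947 and 0.114. Not called in the blocked fit were Cdh1 (-0.33 ± 0.12, adjusted p = 0.134), Krt19 (-0.47 ± 0.19, adjusted p = 0.0779) and Met (0.13 ± 0.23, adjusted p = 0.654), with adjusted p from that fit.

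In the list tests at 24 h, the amino acid response genes stood higher, with 27 of 28 members above control and a median of 0.35. By camera, the list had an adjusted p = 6.14e-07, and adjusted p = 0.499 with an estimated correlation. No member passed one by one without the block, 5 rose adjusted over the list alone, and 5 rose with the block, among them Cth, Phgdh (0.98 ± 0.19, adjusted p = 0.0189), the gene of the enzyme that opens serine synthesis, and Trib3 (1.07 ± 0.48, adjusted p = 0.0423). Ribosome biogenesis genes also stood higher, with 45 of 53 members above control and a median of 0.26. This list had a camera adjusted p = 1.66e-06, and adjusted p = 0.0813 with an estimated correlation. Here 1 member rose with the block, Nop56 (0.75 ± 0.14, adjusted p = 0.0207). Ribosomal protein genes had a median of 0.06. Tested by camera, the list had an adjusted p = 0.0469, and adjusted p = 0.518 with an estimated correlation. With the block its camera adjusted p was 0.0523, and the call held in 2 of 8 fits with 1 array left out in turn. Interferon-stimulated genes had a median of -0.21. In the camera test this list had an adjusted p = 0.0408, and adjusted p = 0.217 with an estimated correlation. With the block its camera adjusted p was 0.0523, and the call held in 4 of 8 fits with 1 array left out in turn. The camera adjusted p of cholangiocyte and progenitor markers fell from 0.0888 to 0.0282 with the block (adjusted p = 0.64 with an estimated correlation; median -0.40; 3 members fell with the block). That of hepatocyte markers fell from 0.0536 to 0.0427 (adjusted p = 0.385 with an estimated correlation; median -0.38; no member called). Mitosis genes had a median of 0.0025 and a mean of -0.0046 (camera adjusted p = 0.803; 2 members fell with the block). The remaining 21 lists had camera adjusted p between 0.0742 and 0.956, and no member of any list was called at 24 h without the block. With the block, the numbers that rose and fell at 24 h were 3 and 3 for immediate early genes, 1 and 1 for MAPK feedback, 2 and 4 for proteases, 2 and 0 for integrins, 2 and 3 for extracellular matrix and 0 and 2 for junctions. They were 1 and 0 for mesenchymal transition, 2 and 1 for actin and SRF targets, 0 and 1 for DNA replication, 0 and 1 for G1 cyclins and inhibitors, 2 and 2 for inflammatory genes and 0 and 3 for interferon-stimulated genes. Of the rest, there were 3 and 4 for growth factors, 0 and 1 for Wnt, Notch and YAP targets, 1 and 0 for FoxO targets, 1 and 0 for ER chaperones and 1 and 5 for oxidative stress.

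Direct comparison of the HGF times, to which the control arrays added only to the estimate of spread, found 1422 genes that differed between 6 h and 1 h, 1087 between 24 h and 6 h and 707 between 24 h and 1 h (1163 for the last with the block). Of the 215 genes higher at 1 h, 98 were also higher at 6 h, 125 were lower at 6 h than at 1 h and 166 lower at 24 h than at 1 h. Of the 177 lower at 1 h, 98 were also lower at 6 h and 110 stood higher at 24 h than at 1 h. From 1 h to 6 h the steepest falls included those of Fosb (-7.96 ± 0.30), Atf3, Egr2 and Fos (-5.31 ± 0.44), and the steepest rises those of Il24 (5.48 ± 0.33), S100a7a (4.29 ± 0.67), Ppbp (3.39 ± 0.40), Edn1 (3.28 ± 0.28) and the receptor accessory gene Ramp3 (3.27 ± 0.36). From 6 h to 24 h, Mmp3 (-6.96 ± 0.21), Mmp10, Mmp13 (-4.82 ± 0.69) and Il24 (-3.99 ± 0.33) fell, and Cdsn (2.82 ± 0.55), Gadd45a (2.49 ± 0.32), the cystine transporter gene Slc7a11 (2.47 ± 0.35) and Ciart (2.45 ± 0.40) rose. From 1 h to 6 h, 10 of 38 mitosis genes fell. Camera gave the list an adjusted p = 2.54e-05, and adjusted p = 0.371 with an estimated correlation. Of the 38 mitosis genes, 36 were higher at 24 h than at 6 h (median 1.24; camera adjusted p = 1.38e-25, and adjusted p = 0.155 with an estimated correlation). Of the 759 genes higher at 6 h, 365 were lower at 24 h than at 6 h, and of the 993 lower at 6 h, 445 were higher at 24 h. Over all 8183 genes, 519 were lower and 568 higher at 24 h than at 6 h. These sets were chosen on the same 6 h arrays that enter the test, which by itself favours a return. The same holds for the sets called at 1 h and the 1 h arrays. With the median scaling, 36.2% of the calls between 6 h and 1 h were higher (48.0% in the main design), and 68.5% of those between 24 h and 6 h (52.3% in the main design). Cyclic loess gave 40.8% and 50.3%, and the test against a 1.5-fold change 34.9% and 35.4%. The 3 counts fell to 551 without HGF 1 h replicate a, 287 without HGF 24 h replicate b and 162 without HGF 1 h replicate a, respectively.

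In total, 196 genes were called in the same direction at 1 h and 6 h, where independent lists would share 41.4. With the block, 404 were, where independent lists would share 106. Simulated unchanged groups against the same controls shared 0.03 without the block on average, but such groups hold few calls to share. That value therefore does not measure how far the shared controls add to the overlap of changed genes. The log2 changes at 1 h and 6 h correlated at 0.417 across genes, which are not independent replicates, against 0.499 in simulated unchanged groups. Their covariance was 0.102 against 0.0186 in the simulation. For 6 h and 24 h the covariance was 0.0915 against 0.0185, and for 1 h and 24 h 0.0376 against 0.0185. The 2 control arrays cannot be split into 2 control groups of 2, so part of the shared calls may come from the shared controls.

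Markers of other liver cell types were mostly not measured above background. Of 13 haematopoietic markers with a probe, 2 were tested, and Cd14, a receptor of bacterial lipopolysaccharide, fell at 6 h (-0.54 ± 0.11, adjusted p = 0.0139) while Coro1a did not pass (adjusted p = 0.0946). Of 14 endothelial markers 1 was tested, Eng (0.66 ± 0.31 at 6 h, adjusted p = 0.168), and of 15 stellate cell and fibroblast markers 0. Of 44 hepatocyte markers 8 were tested. The haem carrier gene Hpx rose at 1 h (2.26 ± 0.20, adjusted p = 0.00119) and 6 h (1.67 ± 0.20), and the transcription factor gene Foxa2 fell at 6 h (-1.01 ± 0.22), with the list called at neither time (camera adjusted p = 0.832 and 0.956). Alb, Afp and Hgf were not detected on both arrays of any group. Among cholangiocyte and progenitor markers, 1 and 0 of 15 rose and fell at 1 h (2 and 0 adjusted over the list alone; 2 and 0 with the block) and 2 and 0 at 6 h (2 and 0 adjusted over the list alone; 5 and 1 with the block). Muc1 rose at both times (0.84 ± 0.13 and 0.51 ± 0.13) and Tnfrsf12a, the receptor of TWEAK, at 6 h (0.67 ± 0.12). Sox9 gave 1.22 ± 0.32 at 1 h (adjusted p = 0.0806, and 0.00676 with the block).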

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

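The results below are flagged because 2 times differ by a test of the difference, or because signal appeared in probes outside the report's comparisons. All tests of explanations in this part were chosen only after the result was seen.

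By the direct test, 1422 genes differed between 6 h and 1 h, 1087 between 24 h and 6 h and 707 between 24 h and 1 h. Of the genes called against control, 14 were called in opposite directions at 1 h and 6 h, 11 up and then down and 3 down and then up. All 14 differed between the 2 times, which opposite calls against the same control largely imply. In opposite directions at 6 h, without the block, and at 24 h, with the replicate letter as a block, 13 genes were called. Among them were Mmp3 (5.09 and -1.87), Ciart (-1.60 and 0.85) and Acot2 (-1.17 and 1.05), chosen after their values were seen. The amino acid response list was called down at 6 h and up at 24 h by camera, with a mean log2 difference of 0.93 between them. With an estimated correlation the camera adjusted p was 0.722 at 6 h and 0.499 at 24 h. The call at 6 h held in 6 of 8 fits with 1 array left out in turn, and not without HGF 6 h replicate a. From 6 h to 24 h, 18 of 28 members rose, 25 adjusted over the list alone (camera adjusted p = 2.37e-11, and adjusted p = 0.274 with an estimated correlation). Among 699 tested probes with no gene symbol, adjusted over these alone, 14 were higher and 15 lower at 1 h, 76 and 77 at 6 h and 2 and 5 at 24 h.

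With the report's normalization, probe filter and variance model, genes passed at 24 h only with the replicate letter as a block. If a difference between the repeats shared by all groups hid them, the lettered pairing should give more calls than the 7 other ways to pair the arrays. It gave 440 against at most 1, as predicted. However, the a minus b difference was already known to correlate between every pair of groups (0.194 to 0.443). The result largely follows from that correlation and is not separate support. False calls from the degree of freedom the block uses should have given the other pairings similar counts, and these gave at most 1. However, those pairings leave a difference between the repeats in the spread, which lowers their counts whether or not the 440 are false. The comparison therefore cannot exclude false calls among them. Whether changes at 24 h were smaller stays open, since fewer genes had a 2-fold difference (114 against 235 at 1 h and 517 at 6 h) but the median absolute log2 change was 0.19 against 0.18 at 1 h.

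Of 38 mitosis genes, 25 fell at 1 h and 35 at 6 h (adjusted p = 0.209 for the list at each time with an estimated correlation), and at 24 h none was called without the block. With cyclic loess the list median was -0.78 at 1 h and -1.18 at 6 h, and with median scaling -0.95 and -1.35. Over all 5 other scaling and background settings the median nearest to 0 was -0.74, without background correction. These values argue against the choice of scaling as the cause, though every setting brings the arrays to a common level. A trend with signal level is excluded, since the lowest of 10000 matched random lists had -0.25 against -0.82 at 1 h and -0.32 against -1.18 at 6 h. Control arrays with unusually high mitotic transcripts should put the 24 h arrays below control too, and the 24 h median was 0.0025. Its 95% bootstrap interval, -0.07 to 0.11, resamples genes and not arrays. A rise of these transcripts by 24 h could hide high controls, so this explanation is not excluded. An even loss of cycling cells should lower DNA replication genes as far, and their median was -0.029 at 6 h (interval over genes -0.18 to 0.08). The value argues against such a loss acting alone. A rise of replication genes at the same time could offset it, so it is not excluded. A change in the cell cycle under HGF, such as a delay before mitosis, remains possible as a hypothesis and was not tested.

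Per1, Per2, Nr1d1 and Bhlhe40, 4 of the 14 genes above, belong to the circadian clock and rose at 1 h (Per1 1.62, Per2 1.19, Nr1d1 1.07, Bhlhe40 1.69) and fell at 6 h (Per1 -1.06, Per2 -1.48, Nr1d1 -0.54), as Bhlhe40 did. Of the 7 other genes of a clock set of 11 assembled after the values were seen, 0 rose at 1 h and 5 fell at 6 h. Handling at the start of stimulation cannot be told apart from HGF, since the design held 0 control groups with their own time point. The same limit holds for every other change against control in this report.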

How the results depend on the processing

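The alternatives were fixed before the files were opened, except the authors' values with the block, the random block and the lists without each array, which were chosen after the result was seen. No called gene or list named in the text turned direction. More genes were lower than higher, against the other way round in the report, at 1 h with the authors' values and the block (463 higher, 521 lower) and from 6 h to 24 h with the test against 1.5-fold (29 higher, 53 lower). Cyclic loess, robust eBayes, no filter and every probe counted kept every count within 1.5 times, and fry gave 31 list calls against 28. With median scaling, 142 genes were higher at 1 h and 322 at 6 h, 713, 663 and 427 differed between 6 and 1 h, 24 and 6 h and 24 and 1 h, 1243 changed at any time and 113 were shared by 1 h and 6 h. At 24 h, no background correction gave 37 higher and 62 lower, the authors' values 26 and 38, the intensity trend 55 and 75, and offset 50 and a detection p of 0.01 each 1 lower. Only the 2 groups compared gave 137 higher and 67 lower at 1 h, 806 between 6 and 1 h, 458 between 24 and 1 h and 87 shared, with fewer arrays. The replicate block gave 375 and 365 at 1 h, 163 and 277 at 24 h, 1163 between 24 and 1 h and 404 shared, and beyond the genes and lists whose blocked values stand beside them in the text, it changed no call of a gene or list printed there. A test against 1.5-fold, stricter by construction, gave 57 and 3 at 1 h, 83 and 83 at 6 h, 146, 82 and 70 between times and 18 shared. The authors' values with the block gave 463 and 521, 1173 and 1546, and 326 and 503 at the 3 times, 2339, 1947 and 1518 between times, 3510 at any time and 523 shared. The random block (correlation 0.122) gave 274 lower at 1 h, 44 and 56 at 24 h and 297 shared. An estimated correlation left 2 list calls. With 1 array left out, where the lone array of its group is assumed to vary like the others, the ranges were 73 to 186 higher and 6 to 139 lower at 1 h, 380 to 709 and 474 to 903 at 6 h, 0 and 0 at 24 h, 551 to 1258, 287 to 1031 and 162 to 643 between times, 992 to 1504 at any time, 35 to 134 shared and 22 to 35 list calls. At 1 h the counts were 73 and 6 without control a, 152 and 99 without control b, 108 and 46 without HGF 1 h a and 95 and 11 without HGF 1 h b. At 6 h they were 412 and 474 without control a, 430 and 565 without control b, 444 and 555 without HGF 6 h a and 380 and 477 without HGF 6 h b. Of 217 called values of named genes, 99 were called under every alternative and 140 without each array in turn. Apart from fewer arrays and the stricter test, the cause was not tested. Signal over background limits the measured genes to 8183 of 16593.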

Other observations

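The gene sets in this part were assembled only after the result was seen, and their p-values are descriptive. At 24 h, 17 measured genes of secretory and brush border epithelium had a median of -1.03, and 11 fell with the replicate block (0 without; adjusted p = 0.490 with an estimated correlation). Gkn2 (-2.54 ± 0.95), Tff3 (-1.66 ± 0.29), Cdhr5 (-1.56 ± 0.26), Lgals4 (-1.43 ± 0.23), Psca (-1.29 ± 0.27) and Vil1 (-1.27 ± 0.37) were among them. In contrast, 12 measured cornified envelope genes had a median of 1.17 at 24 h, 6 rose with the block (0 without; adjusted p = 0.174 with an estimated correlation), and at 6 h 5 rose and 1 fell (6 and 3 with the block; adjusted p = 0.412 with an estimated correlation).

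At 1 h, of 12 measured H2A histone genes 9 fell and 1 rose (median -1.24; adjusted p = 0.412 with an estimated correlation), and of 10 measured H2B histone genes 5 rose and 0 fell (median 0.71; adjusted p = 0.174 with an estimated correlation). Copies of these genes are nearly identical in sequence, so which copy a probe measured is uncertain. Of 160 measured genes with Zfp symbols, 15 fell and 2 rose at 1 h (33 and 5 with the block; median -0.18; camera adjusted p = 0.00158, and adjusted p = 0.470 with an estimated correlation). Clock genes had a median of -1.13 at 6 h, with 9 of 11 lower (adjusted p = 0.174 with an estimated correlation).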
